A study of Mus musculus with 6 samples.

How the data were processed

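RNA was measured in soleus, a postural hindlimb muscle of mixed slow and fast fibres, of 6 mouse libraries. The labels gave 3 libraries as wild type (WT) and 3 as StarD7 mKO, the muscle knockout of the gene for StarD7, a lipid transfer protein. Groups and replicate numbers came from the labels. The series text gave 3 mice per group, while the labels did not tie each library to an animal, so p-values measured the spread between these samples. Per the labels' protocols, RNA was extracted with a Maxwell RSC kit and libraries were made with a directional poly(A) kit (NEBNext Ultra II). Poly(A) selection leaves out transcripts without a tail.

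The authors deposited 1 table of TPM per library, in which reads are divided by gene length and scaled to a fixed sum within the library. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting tool and whether counting used strand were not given in the sources used here. Because TPM has a fixed sum, a group of very abundant genes that rises lowers the value of every other gene. Each table held 43074 gene names. The annotation used here, GENCODE M21, is of an older build, so no coordinates are given and its gene order served only to find the neighbours of Stard7.

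The design fixed before the data were examined assumed raw read tables and named a fallback for normalised values. Since the tables held TPM, the fallback was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(TPM + 1), with genotype as the only term, for the 12301 genes at 1 TPM or more in at least 3 libraries. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. Fold changes are mKO minus WT on the log2(TPM + 1) scale, which understates the change of genes at low TPM. Errors of means are SDs with n = 3, and errors of log2 fold changes are standard errors (SE). DESeq2 and edgeR were not used, since the deposited unit is TPM.

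Depth was worked out from the values. TPM multiplied by the exon length in GENCODE M21 and by a scale for each library gave whole reads, within 0.05 reads, in all 6 libraries for 93.12% of the 22734 genes with a single matching name and a value above 0. Chance would give 10% of values. These genes held 42928774 to 51287999 reads per library. Of the tested genes, 11206 had whole reads. Of all recovered values above 0, 58.55% were even, so a read pair may have been counted as 2 reads at least in part. The reads were used for depth and for limma-voom as an alternative. Pairs of libraries of the same group differed far beyond sampling noise (chi-square per degree of freedom between 23.2 and 45.6), so none was a library deposited again.

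Gene lists were fixed before the data were examined: 46 lists of pathways, fibre types, other cell types and handling stress. Older names were used for members that the tables list under another name, 25 in all. These include 3 numbered entries (of Aldoa, Ddit3 and Atp5po), for which the expressed entry was taken after the values were seen. The 42 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which tests whether a set moves on balance in a single direction, were alternatives. Fry tests a list against no change, not against other genes, and was run only on the main fit. A fixed TPM sum that lowers nuclear genes about alike can therefore give a fry call of a small fall by itself. Shares of transcripts were compared with exact two-sided permutation tests, for which 0.1 is the smallest p that 3 against 3 can give.

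Named genes followed a rule fixed in advance. It took Stard7 and up to 12 genes with the largest change in each direction among those past the threshold, at a mean above 2 TPM and with no overlap between groups, leaving out predicted genes. A gene that the rule picked is not reported here. It then took up to 4 called members of each list, or 2 members given as values where a list had none, and did not require that all be printed. Of the latter members only Nupr1 and Trib3 are printed, a choice made after the values were seen. The adult myosin heavy chains and their shares, Atf4, Trim63, Fbxo32, Gdf15, Fgf21, Smox, Tnnc2 and Mylk2 fall outside the rule and were chosen after their values were seen. Alternatives were other filters and pseudocounts, mitochondrially encoded genes left out, a replicate block, each library left out, and scalings added after seeing the data. The test was checked on simulated reads drawn from the means and spread of the WT libraries, 3 against 3, each gene independently. The spread within mKO was not used, so the rates below need not hold for genes that vary more there. At a log2 change of 1, limma-trend recovered 89.9% of 99 changed genes, and at 2 it recovered all 98, with 8 false calls among 11099 genes.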

Results

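The series measured the transcriptome of soleus muscle in 3 WT and 3 StarD7 mKO libraries, to find which genes differ when the muscle lacks StarD7, a protein that carries phosphatidylcholine to mitochondria. Reads recovered from the deposited TPM came to 51287999, 47171355 and 48189931 in WT replicates 1, 2 and 3, and to 43444393, 47404918 and 42928774 in mKO replicates 1, 2 and 3. Between 19774 and 20207 genes had a value above 0. The mitochondrially encoded genes took 43.6% ± 1.49 of all TPM in WT and 48.0% ± 1.05 in mKO (SD, n = 3 each, exact permutation p = 0.1, the smallest this design allows).

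The targeted gene was lower in each mKO library. Stard7 stood at 87.5, 95.4 and 95.0 TPM in the WT libraries and at 21.8, 21.3 and 34.6 TPM in the mKO libraries. Its mean in mKO, 25.9 ± 7.50 TPM, was 28.0% of the WT mean of 92.6 ± 4.41 TPM. The log2 fold change was −1.83 (SE 0.16, adjusted p = 0.00585, limma). Which exons were deleted is not given in the sources used here, so whether the remaining reads come from a shortened RNA was not tested. The call was lost without WT replicate 2 (−1.81, adjusted p = 0.0703) and with no filter on low values (adjusted p = 0.0858), in a range of 1.58e-05 to 0.0858 over all settings run.

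Of the 12 largest falls that the naming rule took besides Stard7, 4 were of the fast fibre list (Mybpc2, Pvalb, Actn3 and Myoz1), 1 of the list of glycolysis and glycogen use (Slc16a3) and 7 of neither. Mybpc2, the fast isoform of myosin binding protein C, fell from 169 ± 16.4 TPM to 0.647 ± 0.531 TPM (log2 fold change −6.73, SE 0.20, adjusted p = 8.37e-06). Pvalb, the calcium buffer parvalbumin, fell from 713 ± 129 to 14.0 ± 12.4 TPM (−5.87, SE 0.48, adjusted p = 0.00466), and Actn3, the Z-disc protein of fast fibres, fell from 264 ± 54.5 to 14.4 ± 1.32 TPM (−4.08, SE 0.14, adjusted p = 1.42e-05). Slc16a3, a lactate exporter, fell by 2.71 on the log2 scale. Further down this ranking stood Cib2 (−1.73), Tmem233 (−1.65), Mylk4 (−1.54), Tlcd3b (−1.40), Gpd1 (−1.28), Tbc1d1 (−1.16), Myoz1 (−1.12) and Tlcd4 (−1.05). The calls of Mybpc2, Actn3 and Gpd1 held in all 14 other settings, those of Pvalb and Tmem233 in 12, Slc16a3 in 9, Cib2 and Tbc1d1 in 7 and Myoz1 in 4. Of 13 settings that tested them, Mylk4 held in 11, Tlcd3b in 7 and Tlcd4 in 6.

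Fewer genes rose. Pln, which encodes phospholamban, the inhibitor of the slow-fibre and cardiac calcium pump, rose from 4.30 ± 0.528 to 14.2 ± 1.02 TPM (log2 fold change 1.52, SE 0.09, adjusted p = 0.000742). Cyfip2 rose by 1.24, Prune2 by 0.96, the BMP antagonist Nog by 0.84, and the extracellular superoxide dismutase Sod3 by 0.74, from 10.8 ± 0.497 to 18.8 ± 2.91 TPM. Tmco4 (0.52), Pcp4l1 (0.46) and Dffa (0.34) rose by less. The call of Pln held in all 14 other settings and that of Cyfip2 in 11, while Sod3 held in 7, Nog, Tmco4 and Dffa in 6, Pcp4l1 in 5 and Prune2 in 4. The calls of Nog, Tmco4 and Dffa were lost whichever library was left out. In all, limma-trend called 64 of 12301 genes, 12 higher and 52 lower in mKO, of which 21 changed at least 2-fold on the log2(TPM + 1) scale. That scale leaves out some genes over 2-fold in TPM, such as Prune2 (2.08 times WT) and Nog (2.05 times). None of the 64 had overlapping groups. Among all tested genes 16.01% did not overlap, where chance gives 10%. The number of calls was 13, 4 and 12 without WT replicates 1, 2 and 3, and 13, 26 and 94 without mKO replicates 1, 2 and 3. Those of at least 2-fold numbered 12, 4 and 9, and 12, 15 and 32. With mitochondrially encoded genes left out and TPM rescaled, 41 genes were called, 21 higher and 20 lower, so 51.22% of calls were higher in place of 18.75%, and the median log2 fold change of all genes moved from −0.01 to 0.09.

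**Figure D1:**
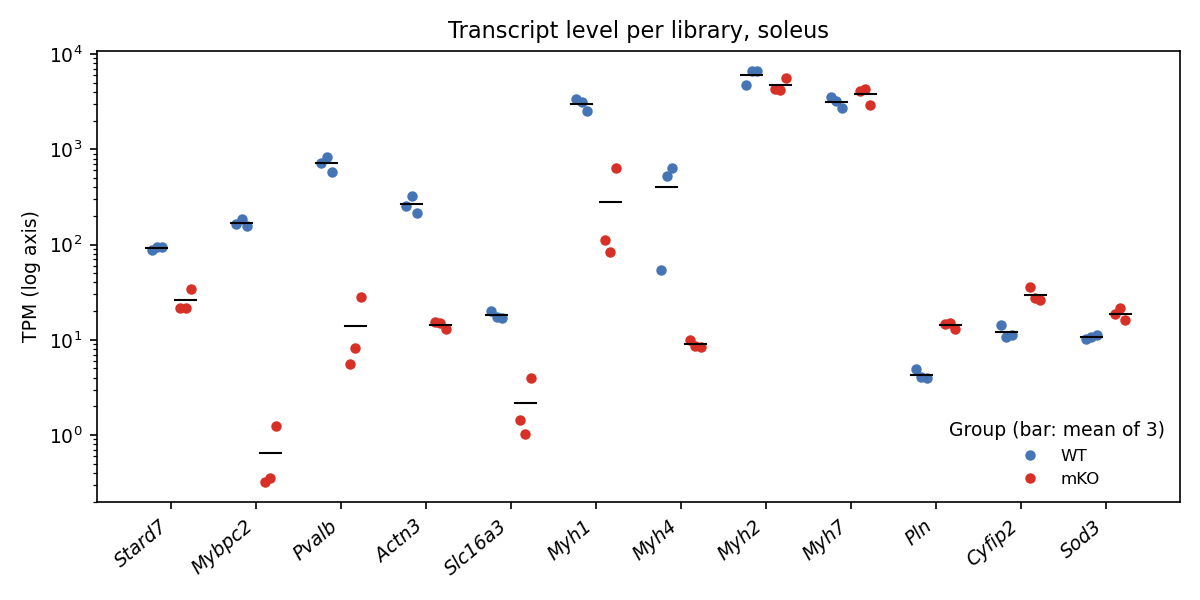
TPM on a log axis of 12 genes in soleus, each point a library (3 WT in blue, 3 mKO in red) and each bar the mean of 3. Stard7 fell to 28.0% of WT, Mybpc2, Pvalb and Actn3 fell much further, and Pln, Cyfip2 and Sod3 rose. Myh1, Myh4, Myh2 and Myh7 did not pass the test.

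Of 18 fast fibre genes tested, 6 fell and none rose, and 17 fell when adjusted over the list alone. All 18 had a log2 fold change below 0, with a median of −0.62. Besides Mybpc2, Pvalb, Actn3 and Myoz1, the calls were Tnnc2, fast troponin C, at −0.49 and Mylk2, the skeletal myosin light chain kinase, at −0.38, which held in 1 and 2 of 14 other settings. The list was lower than other genes by camera (adjusted p = 9.92e-29), and with an estimated correlation the adjusted p was 0.298. By fry, which tests the list against no change, the adjusted p was 0.0262. Of 15 slow fibre genes, Pln alone rose, both over all genes and adjusted over the list alone, and the median of the list was 0.24. Leaving out 1 library moved this median to 0.09 without WT replicate 3, 0.15 and 0.14 without mKO replicates 1 and 2, and 0.43 without mKO replicate 3. Camera put this list higher (adjusted p = 0.000425, and adjusted p = 0.707 with an estimated correlation). Myh7, the slow myosin heavy chain, had a log2 fold change of 0.24 (SE 0.16, adjusted p = 0.661).

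The myosin heavy chains, which define the fibre types, were lower for the fastest types in value but did not pass the test. Myh1, the type IIx chain, stood at 3008 ± 461 TPM in WT and 277 ± 311 TPM in mKO, and Myh4, the type IIb chain, at 406 ± 309 and 8.98 ± 0.905 TPM. Neither passed the threshold (log2 fold changes −4.03 and −4.73, adjusted p = 0.0515 and 0.0576, limma). Myh2, the type IIa chain, was at −0.33 (adjusted p = 0.527). As a share of the 4 adult transcripts, Myh1 made up 24.1% ± 4.59 in WT and 3.06% ± 3.34 in mKO, a difference of −21.1 points. Myh7 made up 25.3% ± 4.40 and 43.2% ± 10.2, and Myh2 47.4% ± 6.58 and 53.7% ± 6.88. The exact permutation p was 0.1 for Myh1, Myh4 and Myh7, the smallest this design allows, and 0.4 for Myh2. These chains are near-identical in stretches, and reads shared between them could be counted to another.

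**Figure D2:**
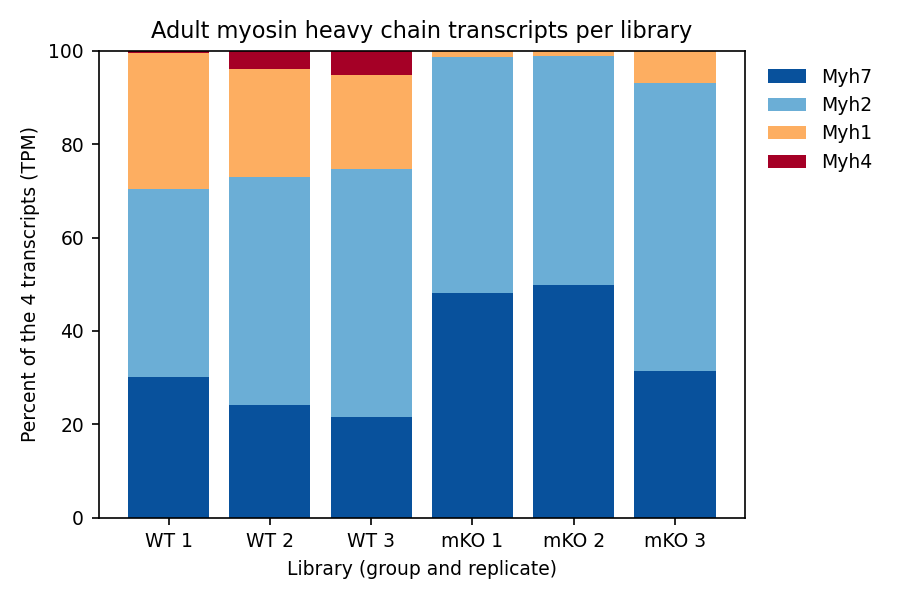
Share in percent of the 4 adult myosin heavy chain transcripts (TPM) in each of the 3 WT and 3 mKO libraries, as stacked bars from 0 to 100. Myh1 took 20.1% to 29.1% in WT and 0.964% to 6.91% in mKO.

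Of 30 genes of glycolysis and glycogen use tested, 4 fell and none rose, and 16 fell when adjusted over the list alone. The calls were Slc16a3, Pygm, the muscle glycogen phosphorylase (−0.65), Pfkm, muscle phosphofructokinase (−0.43), and Ldha, lactate dehydrogenase A (−0.38), of which the last 3 held in 3, 3 and 4 of 14 other settings. The median was −0.24 (camera adjusted p = 7.33e-09, adjusted p = 0.298 with an estimated correlation), and −0.13 with mitochondrially encoded genes left out. Of 19 genes of calcium handling and excitation, 2 fell, the ryanodine receptor Ryr1 (−0.38) and the calcium channel subunit Cacng1 (−0.51), and 7 fell when adjusted over the list alone. These 2 calls held in 2 and 6 of 14 other settings. The median of the list was −0.13 (camera adjusted p = 1.74e-05, adjusted p = 0.298 with an estimated correlation), and −0.02 with mitochondrially encoded genes left out. In that setting the median of all genes moved from −0.01 to 0.09. The camera calls of glycolysis (adjusted p = 7.16e-10) and calcium handling (0.0015) stayed, both lists being lower relative to the other genes.

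Nuclear genes of the respiratory chain stood slightly lower than other genes as groups, with no single member past the threshold. All 36 complex I genes were below 0, with a median of −0.12 (camera adjusted p = 3e-12, adjusted p = 0.298 with an estimated correlation), and so were all 10 genes of complex III (median −0.12, adjusted p = 9.38e-05, 0.298 with an estimated correlation) and all 15 of complex IV (median −0.12, adjusted p = 0.000247, 0.674 with an estimated correlation). Complex V had 18 of 19 genes below 0 (median −0.12, adjusted p = 1.34e-07, 0.298 with an estimated correlation). Adjusted over the list alone, 5 genes of complex I, 2 of complex III, 4 of complex V and 0 of complex IV fell. The 13 mitochondrially encoded genes had a median of 0.10, 12 of them above 0, with 0 called over all genes and 2 higher when adjusted over the list alone (camera adjusted p = 0.000116, adjusted p = 0.573 with an estimated correlation). That list call was lost with no filter on low values (adjusted p = 0.188). The median of complex IV was −0.07 without WT replicate 2 and without mKO replicate 3, and that of the mitochondrially encoded genes 0.15 without WT replicate 3. With mitochondrially encoded genes left out, the calls of complexes III and IV were lost (adjusted p = 0.0657 and 0.242), while those of complex I (0.00121) and complex V (0.00579) stayed, each p being the highest over the settings run with a preset correlation. Under that rescaling, which raises nuclear genes about alike whatever the cause, the median of all genes moved from −0.01 to 0.09. The medians became −0.01 for complexes I and III and 0.00 for IV and V, which crossed 0. Under it these groups were lower only relative to the other genes. With scaling by median of ratios, added after seeing the data, all 4 calls held (highest camera adjusted p = 0.00172). The medians then lay from −0.11 to −0.10.

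**Figure D3:**
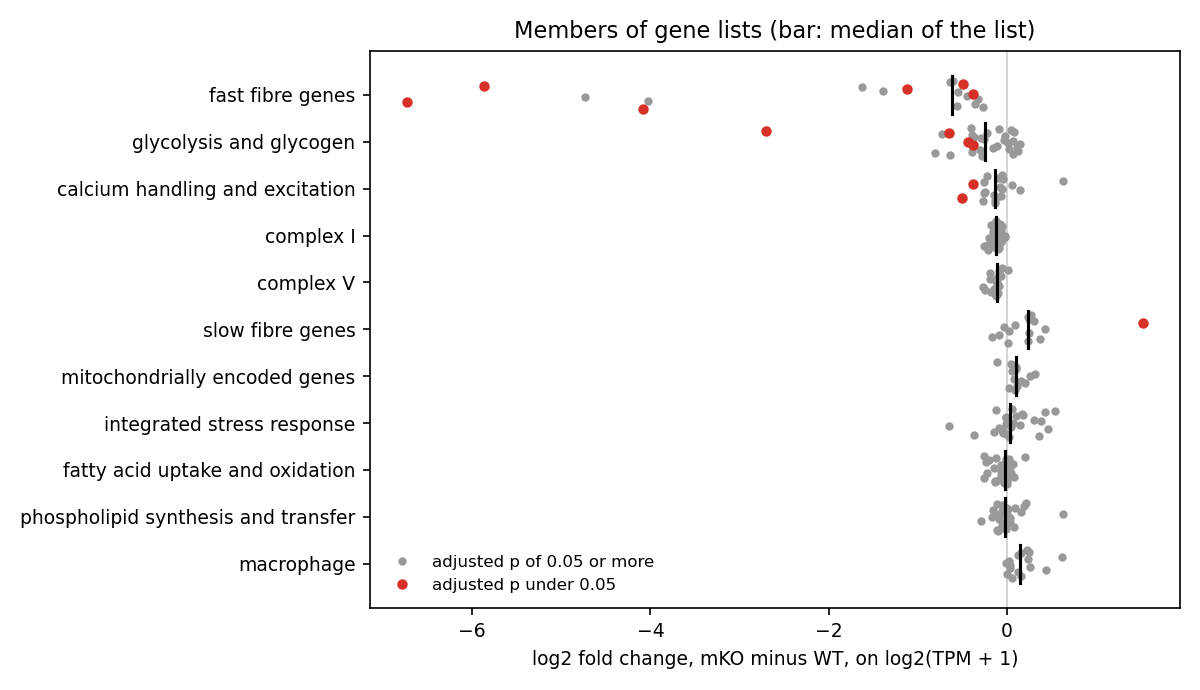
Log2 fold change, mKO minus WT on log2(TPM + 1), of the members of 11 gene lists, each point a gene, red where the adjusted p was under 0.05, with a bar at the median of the list. The fast fibre list reached −6.73 with a median of −0.62, while the members of complex I all lay between −0.26 and −0.02.

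Other mitochondrial and ribosomal groups were lower than other genes by small amounts and held no called gene. Camera's adjusted p was 0.00049 for the TCA cycle (median −0.08), 0.00242 for mitochondrial chaperones and proteases (−0.09) and for mitochondrial ribosomal proteins (−0.06), 0.00429 for mitochondrial dynamics and cristae (−0.07), and 1.05e-05 for cytosolic ribosomal proteins (−0.09). With an estimated correlation the adjusted p was 0.573 for the chaperones and for dynamics, and 0.707 for the other groups. With mitochondrially encoded genes left out each of these calls was lost and each median crossed to above 0. That rescaling raises nuclear genes about alike, and the median of all genes was then 0.09. With scaling by median of ratios, added after seeing the data, each of these calls held (highest camera adjusted p = 0.0142). The medians then lay from −0.07 to −0.05. Adjusted over the list alone, 4 genes of dynamics and cristae and 1 cytosolic ribosomal gene fell. The call of the TCA cycle was lost without WT replicate 3 (adjusted p = 0.112) or mKO replicate 2 (0.0696), that of dynamics without the same libraries (0.072 and 0.0696), and that of cytosolic ribosomal proteins without WT replicate 1 (0.0666, median −0.05). Without WT replicate 3 the median of the latter was −0.16 (adjusted p = 1.43e-22). The median of the TCA cycle was −0.13 without WT replicate 1, and that of the chaperones −0.06 without WT replicate 2. Of 21 atrophy genes, Mstn, which encodes the muscle growth inhibitor myostatin, fell from 1.61 ± 0.162 to 0.123 ± 0.0929 TPM (−1.22, a call that held in 9 of 10 other settings), and 3 fell when adjusted over the list alone (median −0.08, which crossed to 0.04 with mitochondrially encoded genes left out, camera adjusted p = 0.0269, adjusted p = 0.64 with an estimated correlation). The list call was lost without any of WT replicates 1, 2 and 3 or mKO replicate 1 (adjusted p = 0.0572, 0.127, 0.309 and 0.0793), and with a filter at a mean TPM of at least 1 (0.122). Mstn reached 1 TPM only in the 3 WT libraries. It was therefore not tested, alone or in the list, when a WT library was left out or with that filter. Its tally of 10 settings leaves these out. Without mKO replicate 1 the median of the list was −0.01. The ubiquitin ligase genes Trim63 (−0.61, adjusted p = 0.217) and Fbxo32 (0.13, adjusted p = 0.561) did not pass.

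The integrated stress response, often raised in mitochondrial muscle disease, held no called gene among 26 tested by limma, nor when adjusted over the list alone. Atf4 stood at 144 ± 13.8 TPM in WT and 143 ± 7.39 TPM in mKO. Nupr1 had a log2 fold change of 0.38 (adjusted p = 0.224), and Trib3 stood at 2.11 ± 0.643 and 3.48 ± 0.628 TPM (adjusted p = 0.301). The median of the list was 0.03 (camera adjusted p = 0.0182, adjusted p = 0.674 with an estimated correlation), and the call was lost without WT replicate 2, mKO replicate 2 or mKO replicate 3 (adjusted p = 0.0955, 0.0608 and 0.0793). The median was 0.16 with mitochondrially encoded genes left out, 0.07 without WT replicate 1 and 0.01 without mKO replicate 3. Gdf15, below the filter, stood at 0.411 ± 0.0361 TPM in WT and 0.909 ± 0.335 TPM in mKO (adjusted p = 0.484 with no filter), and Fgf21 was listed at 0 in all mKO libraries and in WT replicate 2. Genes of phospholipid synthesis and transfer (28 tested, median −0.02, camera adjusted p = 0.989), coenzyme Q synthesis (13, −0.05, 0.191) and fatty acid uptake and oxidation (33, −0.03, 0.22) held no called gene, nor did any pass when adjusted over the list alone. Camera put the fatty acid list lower without mKO replicate 1 (adjusted p = 0.00163, median −0.07) and in no other setting with a preset correlation.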

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

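The scalings by median of ratios and by upper quartile, the read-based share of Myh1 and, for gene lists, the other filter, pseudocount and mitochondrial settings were chosen after seeing the data. No tested call changed direction under any setting run, where the direction of a list is that given by the list test. Medians of small list effects did cross 0 with mitochondrially encoded genes left out. So did those of macrophage and fibroblast markers without mKO replicate 2, and of sterol synthesis without WT replicate 3. All tested members of the 64 calls kept their sign in each setting. With no filter 6 genes were called, 2 higher, 4 lower and 5 at least 2-fold, over 24964 genes tested, and the cause was not tested. Stard7 then had an adjusted p of 0.0858 at −1.83. Mitochondrially encoded genes left out gave 41 calls, 21 higher and 20 lower, and 32 of the 64 remained. Median-of-ratios scaling gave 41 calls with 30 lower, and upper-quartile scaling 39 with 29 lower; the cause was not tested. Limma-voom on recovered reads called 60 genes, 42 of them among the 56 calls it could test. Leaving out each library in turn, with fewer samples, gave 4 to 94 calls (without WT replicate 2 and mKO replicate 3), 1 to 18 higher, 3 to 76 lower and 4 to 32 at least 2-fold. Stard7 then lay between −2.05 and −1.72, and its call was lost only without WT replicate 2 (−1.81, adjusted p = 0.0703). The difference in the share of Myh1 was −18.45 points from reads and −21.1 from TPM. Of the 20 list calls, 0 held with an estimated correlation. Fry called 8, 7 of the 20 and complex II (adjusted p = 0.0442). The 7 were fast fibre genes, calcium handling and complexes I, III and V (0.0262 each), glycolysis (0.0286) and mitochondrially encoded genes (0.0496). A fixed sum could give the smaller falls. The scalings of raw counts planned within edgeR and the DESeq2 test were not run, since the deposited unit is TPM, and the 2 scalings above were applied to TPM. Of genes printed without a call, Atf4 (−0.01) lay at 0.11 with mitochondrially encoded genes left out, 0.00889 by limma-voom, 0.00882 and 0.0113 by the scalings, 0.0683 and −0.0522 without WT replicates 1 and 2 and 0.0333 without mKO replicate 1. Prkag1 (−0.05) and Prkag2 (−0.09) moved to 0.0636 and 0.00327 with mitochondrially encoded genes left out. Some of the 115 genes followed through the settings gained a call that they lacked in the main fit. These were 4 without mKO replicate 3, 2 with the replicate block, 1 without WT replicate 1 and 1 with mitochondrially encoded genes left out.

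With the replicate number as a block (replicate block), 21 genes were called, 5 higher and 16 lower, 18 of them among the 64. Of the rises named above only Pln and Cyfip2 kept their call, and the others had adjusted p from 0.0621 (Pcp4l1) to 0.108 (Prune2). Of the falls, the calls of Cib2, Tbc1d1, Myoz1, Tlcd4, Tnnc2, Mylk2, Pygm, Pfkm, Ldha, Ryr1, Cacng1, Mstn, Prkag3 and Smox were lost too (adjusted p from 0.0535 for Cib2 to 0.102 for Tnnc2). The numbers were not taken as pairs: deviations of same-numbered libraries correlated at 0.095, 0.0474 and 0.131 across genes, although each WT library correlated best with its own number, a hint from the data and not from the design.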

Other observations

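The carry-over test, both tests of mKO replicate 3, the tests of the medians of fast fibre and complex I genes, and the isoforms given in the next paragraph were chosen only after the results were seen, as were the genes named there. The comparison with the leading WT library, and the bound put on it, were also set after its outcome.

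Of the gamma subunits of AMP-activated kinase, Prkag3, the isoform of glycolytic muscle, fell (−0.61, adjusted p = 0.0445, a call that held in 5 of 14 other settings), with Prkag1 at −0.05 and Prkag2 at −0.09. Ldha fell by 0.38, and Ldhb stood at 0.14 (adjusted p = 0.467). The difference between isoforms was not tested.

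Markers of other cell types held no called gene. Macrophage (median 0.14, camera adjusted p = 0.00459) and fibroblast markers (0.14, adjusted p = 0.0162) were higher as lists, and so were sterol synthesis (0.06, adjusted p = 0.0326) and embryonic genes (0.22, adjusted p = 0.0455), each with adjusted p = 0.707 with an estimated correlation. Without mKO replicate 2 the medians of macrophage and fibroblast markers were −0.06 and −0.03, and without WT replicate 3 that of sterol synthesis was −0.03. The macrophage call passed in 10 of 13 settings with a preset correlation, the fibroblast call in 11 and the sterol call in 6, and each was lost with mitochondrially encoded genes left out (adjusted p = 0.178, 0.119 and 0.27). Without mKO replicate 1 the macrophage median was 0.36, and without mKO replicate 3 the call was lost (adjusted p = 0.0606). The embryonic call passed in 5 of these settings (adjusted p from 0.00124 to 0.625), and its median was 0.06 without WT replicate 3 and 0.08 without mKO replicate 2. Adjusted over the list alone, 1 fibroblast gene passed and 0 of the others. Among lists that camera did not call, the adjusted p was 0.0901 for complex II, 0.152 for tendon, 0.158 for denervation, 0.191 for adipocyte, erythroid and ER stress genes, 0.193 for extracellular matrix, 0.22 for immediate early genes, 0.316 for satellite cells, 0.365 for smooth muscle, 0.431 for antioxidant genes, 0.481 for mitochondrial biogenesis and Schwann cells, 0.482 for endothelium, 0.552 for interferon genes, 0.64 for autophagy, 0.657 for serine and one-carbon synthesis, and 0.9 for lipid droplets and ferroptosis. Of all 22 lists that camera did not call, 11 passed in at least 1 other setting with a preset correlation. The lowest adjusted p was 4.54e-08 for extracellular matrix (without mKO replicate 2, median −0.31, against 0.05 without mKO replicate 1), 0.00012 for erythroid, 0.00163 for fatty acid oxidation, 0.00167 for tendon, 0.00369 for ER stress, 0.00407 for immediate early, 0.00905 for adipocyte, 0.0142 for smooth muscle, 0.0337 for complex II, 0.0388 for denervation and 0.0488 for antioxidant genes. Adjusted over the list alone, 4 immediate early genes were higher and 2 lower, 1 denervation gene was higher and 1 lower, 2 antioxidant genes were higher and 1 satellite cell gene was lower, with 0 in the other lists named in the preceding sentence. The medians of the antioxidant, biogenesis, autophagy, lipid droplet and ferroptosis lists were below 0 where camera's direction was up.

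The real split of the 6 libraries called 64 genes and the highest of the other splits called 3, with 1 of 10 splits reaching 64, and 10 splits are too few to exclude chance. Within 10000000 bases of Stard7, 1 of 159 tested genes was called, Smox (a call that held in 6 of 14 other settings; 0.629%, against 0.52% of all tested genes, Fisher's exact p = 0.56). That rate lay between the bounds set before the test, so strain variants carried with the modified gene cannot be told apart from an effect of the knockout for this gene; the other 62 called genes lie outside that window.

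The fall of fast fibre genes may reflect scaling, since mitochondrially encoded genes took more of the TPM in mKO. With those genes left out, the median of the list was still −0.50, against −0.62 with them, which argues against scaling as the whole cause, as does its distance from the median of all genes (−0.595), which a fixed sum leaves about unchanged and so cannot create. Between WT libraries Myh4 varied 11.8-fold and Mybpc2 1.20-fold, which goes against carry-over of a single fast muscle as the source of both. That gap rests on WT replicate 1, without which both varied 1.20-fold, so carry-over in the WT dissections cannot be told apart from a loss of fast fibres in mKO. A loss of type IIx and IIb fibres without StarD7 remains a hypothesis that RNA from whole muscle does not test.

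The library mKO replicate 3 lay nearer to WT, with the highest Stard7 and Myh1 of its group. WT RNA mixed into it would give a like share for each gene, yet 4 of 5 strongly lost genes gave under 50% of the share of Stard7 (18.3%), with Mybpc2 at 0.545% and Pvalb at 3.03%, which argues against mixing, although Myh1 gave 18.5%. Of the 52 lower genes, 59.6% had their highest mKO value in replicate 3. In WT the leading library held 46.15% of the same genes, and genes vary together, so this share cannot be told apart from chance. A less complete knockout in that sample may be a cause and was not tested. WT replicate 1 likewise lay nearer to mKO. On the first principal component, the axis of largest variation between libraries, it stood at −6.39, against −13.8 and −13.0 for the other WT libraries. There mKO replicate 3 stood at 5.53, against 13.7 and 13.9 for the other mKO libraries. A library lying towards the other group was thus not particular to mKO.

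Complex I transcripts were lower while mitochondrially encoded ones were higher. A fixed TPM sum could cause this, because a larger mitochondrial share lowers all nuclear genes. Without the mitochondrially encoded genes the median of complex I moved from −0.12 to −0.00513, the outcome predicted for a fixed sum. Leaving them out raises nuclear genes about alike whatever the cause, so this move cannot decide. The median of all genes moved from −0.01 to 0.09. With scaling by median of ratios the median of complex I was −0.11 (camera adjusted p = 2.5e-09). A fixed sum moves nuclear genes about alike, so the distance of complex I from the median of all genes, −0.109 before and −0.0983 after, argues against it for that part. Whether the distance exceeds chance stays open. Camera with an estimated correlation gave an adjusted p = 0.298, but it called 0 lists and gave the fast fibre list the same value. Its lack of a call therefore does not decide this.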
